A study of Homo sapiens with 6 samples.

How the data were processed

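Gene expression was measured in KYSE150, an established human esophageal squamous cell carcinoma cell line, on 6 single-colour Agilent arrays. Per the labels, 3 arrays carried RNA of cells given a negative control siRNA (siNC) and 3 carried RNA of cells given an siRNA against circTNRC6B, a circular RNA named after the gene TNRC6B (sicircTNRC6B), each from a separate biological replicate. The p-values given here therefore measure the spread between biological replicates as labelled. Among the siNC arrays that spread also holds a difference of slide and scan run, described below, which the fit by group alone does not separate. The labels are not uniform: the series' design text names the treatment siTNRC6B without the prefix for a circular RNA, and the molecule is labelled polyA RNA while the protocols describe total RNA. Per the labels' protocols, total RNA was extracted with a phenol and column kit with DNase treatment, reverse transcribed and transcribed into Cy3-labelled cRNA. The siRNA sequences and the time after transfection were not given in the sources used here.

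Each array held 62976 spots, of which 60901 were not controls, for 58201 different probes of 60 bases. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1, and the processed intensity of each spot was its Cy3 signal after subtraction of the local background and a spatial trend, with substitute values for spots near background. The deposited files also held the mean spot intensity and the median local background intensity as scanned. The other columns used were deposited flags of 0 or 1 for spots well above background, non-uniform spots, outliers within a set of repeated spots and saturated spots. A deposited value table of the whole series held log2 values that followed log2 of the processed intensity on each array and had nearly the same distribution on all 6 arrays, as quantile normalization gives; the tool behind it was not given in the sources used here.

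Values were log2 processed intensity minus the 75th percentile of each array, after non-uniform and outlier spots were left out and spots of the same probe were averaged. No spot was saturated: the number of saturated non-control spots was 0 on every array. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 23180 probes. Names came from the accession each file gives for a probe, looked up in a RefSeq table of assembly GRCh38.p14 that was used for names alone; 31104 probes were named by accession, 3366 by symbol, 496 by an older symbol, and 23235 stayed unnamed. Where several probes measured a gene, the one with the highest mean signal stood for it, so that 13805 named genes and 4404 unnamed probes were tested. Of 3877 genes with several tested probes, 1755 (45.3%) had probes whose differences had opposite signs. Probe positions are those of the files, on genome build hg19.

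The only comparison of the design, sicircTNRC6B against siNC, was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with two-sided tests and Benjamini-Hochberg adjustment over all 18209 features and a threshold of 0.05. Differences are log2 sicircTNRC6B minus siNC. Single values were also compared with an exact permutation test, whose smallest possible two-sided p with 3 arrays against 3 is 0.1. The number of arrays limits the precision. For the 31 gene lists, written before the data were examined, limma's camera was run with a preset correlation of 0.01 on the 30 lists with at least 5 tested members, then with an estimated correlation, and limma's fry was run on the same lists. The lists covered pathways of squamous and transformed cells, responses to transfection and stress, and markers of fibroblasts, leukocytes and endothelium, which a cell line should lack. The genes named below follow a rule fixed before the data were examined. It takes TNRC6B, its paralogs, the Argonaute genes and DAG1 whatever their values, and the 10 largest rises and 10 largest falls past the threshold among genes separated between groups and above background on all 6 arrays. If fewer than 20 genes passed, those with the smallest p were to be given and said not to pass. It adds up to 4 members of each gene list past the threshold, 1 member of any other list, and up to 5 genes above background in a single group. Some list members this rule names are not reported here. For a gene above background on all arrays of one group and on none of the other, the difference is a bound: the bright group's mean over the dim group's mean, in which each dim array takes the higher of the probe's own value and the lowest value among probes well above background.

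The fit was tested on simulated data with the arrays' own spread, on the 18197 features with a value on all 6 arrays, which camera and fry used as well. Among 200 genes changed in each simulation, the threshold recovered 0 at a fold of 1.5, 0 at a fold of 2, and 190 (95%) at a fold of 4. False calls were 0 at a fold of 1.5, 1 of 1 call at a fold of 2 and 15 of 205 calls at a fold of 4. The simulated noise was independent for each gene and array, with no slide effect, probe trend or correlation between genes. The real arrays differed in these respects, so the counts need not hold for them. Slides and scans were read from the headers: siNC replicate 1 and the 3 sicircTNRC6B arrays shared slide 1 (4 arrays), and siNC replicates 2 and 3 shared slide 2, scanned in another run. The alternatives tried were normexp background correction (offset 50), quantile normalization, median scaling, the deposited log2 table, other filters on dim probes, outlier spots kept, the mean of a gene's probes, eBayes with trend and robust options, replicate number as a block, slide as a block, and each array left out. Slide as a random block, slide 1 alone, and removal of each array's trend over probe GC content and signal (loess span 0.5) were added after the data were seen, as was camera with an estimated correlation under each of the other settings. Unnamed probes were counted and are not described further.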

Results

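The data were 6 arrays of KYSE150 esophageal squamous carcinoma cells, 3 with the control siRNA and 3 with the siRNA against circTNRC6B. The series set out to screen for genes downstream of this circular RNA. Between 40.7% and 43.9% of the probes were well above background on each array.

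The mRNA of TNRC6B, the host gene, whose protein is a scaffold of microRNA-guided silencing, had a lower mean in the sicircTNRC6B arrays. Its probe A_23_P6490 lies on chromosome 22 at 40719222 to 40719281 (hg19), and the sources used here do not say which exon that is. Normalized log2 signal was 2.32 ± 0.05 (SD, n = 3) in siNC and 1.96 ± 0.10 (SD, n = 3) in sicircTNRC6B, and all 3 sicircTNRC6B arrays lay below all 3 siNC arrays. The log2 difference of -0.36 (SE 0.16) had an adjusted p of 0.644 by limma and an exact two-sided permutation p of 0.1, the smallest this design allows. Within slide 1 the difference was -0.31. The number of probes named for a circular RNA was 0, and probe sequences were not compared with the junction of circTNRC6B, so its level is not reported.

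The partners of TNRC6B in the silencing complex showed no difference past the threshold by limma. The log2 differences were -0.44 (SE 0.31) for the paralog TNRC6A and 0.12 (SE 0.42) for the paralog TNRC6C. Among the Argonaute genes they were 0.25 for AGO1, -0.21 for AGO2, -0.17 for AGO3 and -0.21 for AGO4, with standard errors from 0.18 to 0.19. DAG1, which encodes dystroglycan, had a log2 difference of -0.030 (SE 0.20). Adjusted p-values of these 7 genes ran from 0.731 to 0.968. With normexp background correction the differences were -0.14 for AGO2, -0.076 for AGO3 and -0.12 for AGO4. The signs for AGO1, AGO3, AGO4, TNRC6C and DAG1 were opposite within slide 1, at -0.030, 0.023, 0.010, -0.31 and 0.12. Of 27 tested members of the small RNA silencing machinery, 15 had a positive and 12 a negative difference, and the member with the smallest p was CNOT6, a deadenylase of the CCR4-NOT complex, at -0.61 (adjusted p = 0.642 by limma).

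The ranking below covers genes separated between groups and above background on all 6 arrays. Those with the smallest p for a higher level in sicircTNRC6B included hypoxia-responsive genes, muscle troponins and a glucose-responsive arrestin. Those for a lower level included a Wnt inhibitor and a retinoic acid synthesis enzyme. CA9, the hypoxia-induced carbonic anhydrase IX, had a mean 3.00-fold higher in sicircTNRC6B, NDRG1, also induced by hypoxia, 2.63-fold, and TNNI2, the fast skeletal troponin I, 2.57-fold. With normexp background correction the log2 differences of CA9 and TNNI2 shrank to 1.14 and 0.65. DKK1, the secreted Wnt inhibitor, had a log2 difference of -0.76 and ALDH1A3, a retinaldehyde dehydrogenase, of -0.74. On hg19 the probes lie on chromosome 9 at 35677817 to 35679204 for CA9 (A_23_P157793), on chromosome 8 at 134249719 to 134249778 for NDRG1 (A_23_P20494), and on chromosome 10 at 54076687 to 54076746 for DKK1 (A_23_P24129). None of these 5 genes passed the threshold: limma called 0 of 13805 named genes and 0 of 4404 unnamed probes, with a smallest adjusted p of 0.585. At an unadjusted p under 0.05 there were 847 named genes (6.14%), 503 higher and 344 lower in sicircTNRC6B, and with trend and robust options limma called 0 and had 805 at that level. Median scaling in place of the 75th percentile called 9 named genes, 2 higher and 7 lower. The arrays of the groups did not overlap for 1435 of 13795 named genes (10.4%), where chance gives 10%.

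In the higher set, the log2 differences (SE) were 1.36 (0.19) for TNNI2, 1.58 (0.23) for CA9, 1.14 (0.17) for ARRDC4, an alpha-arrestin gene that responds to glucose, and 0.99 (0.16) for GPNMB, a transmembrane glycoprotein gene. BBOX1, which encodes the last enzyme of carnitine synthesis, had 1.09, TNNT3, the fast skeletal troponin T, 1.35, and INPP5D, which encodes the inositol phosphatase SHIP1, 1.12. The complement gene C4B had 0.91, NDRG1 1.39 and DIP2C 0.84. In the lower set, ATP6V1G2, a subunit gene of the vacuolar proton pump, had -1.34 (0.23), MYEOV -0.97 (0.19), GNE, the key enzyme of sialic acid synthesis, -0.81 (0.16) and ALDH1A3 -0.74 (0.16). SPRR2C, a transcribed pseudogene of the cornified envelope gene cluster, had -1.08, SFTA1P, a noncoding transcript, -0.78 and DKK1 -0.76. The T cell marker CD8A had -1.56, the potassium channel gene KCND3 -0.85 and PITPNC1, a phosphatidylinositol transfer protein gene, -0.84. These 20 genes were those with the smallest p, and all had an adjusted p of 0.585 by limma. For SFTA1P a probe of lower signal gave 1.54, opposite to the probe used. With normexp background correction the differences shrank for most of these genes: to 0.65 for TNNI2, 0.58 for GPNMB, 0.56 for BBOX1, 0.47 for TNNT3, 0.28 for C4B and 0.30 for DIP2C. In the lower set they shrank to -0.45 for ATP6V1G2, -0.54 for MYEOV, -0.42 for SPRR2C, -0.56 for CD8A, -0.51 for KCND3 and -0.29 for PITPNC1. Within slide 1, against the single siNC array there and for genes chosen by their p over both slides, the differences were 1.41 for CA9, 1.24 for NDRG1, 1.41 for TNNI2, 1.03 for ARRDC4, 0.95 for GPNMB, -0.76 for DKK1, -0.67 for ALDH1A3 and -1.02 for MYEOV, while SPRR2C and CD8A had -0.63 and -0.74. The choice also required every sicircTNRC6B array to lie beyond every siNC array, siNC replicate 1 included. The signs within slide 1 were therefore fixed by the choice and lend these genes no support.

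**Figure D1:**
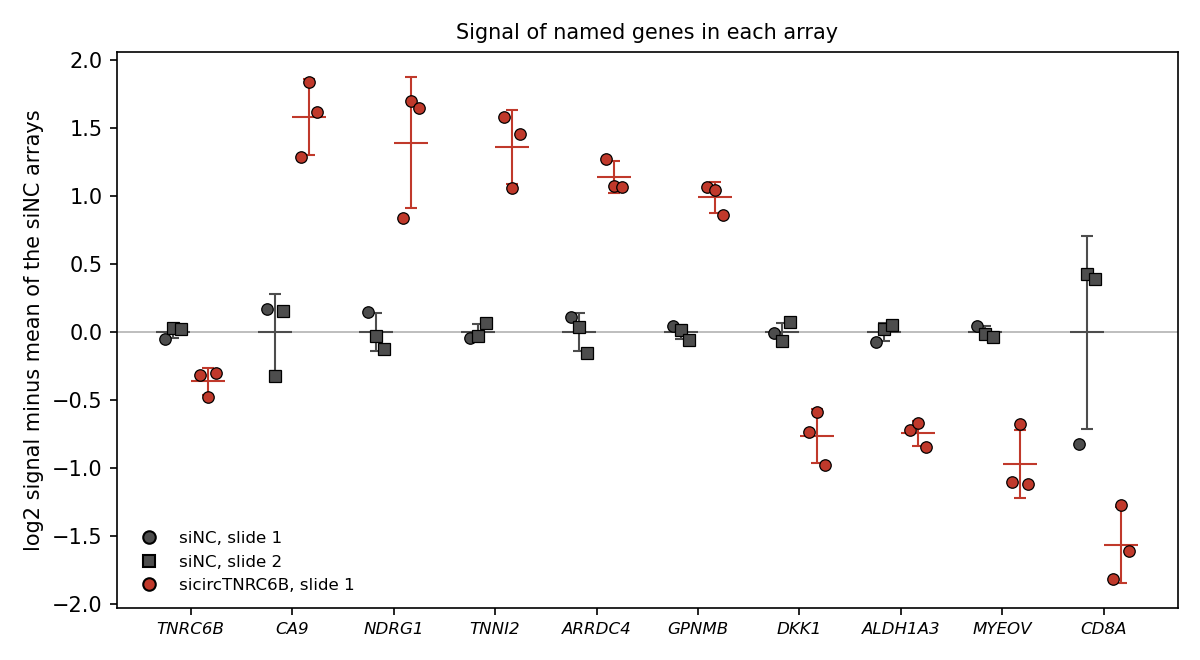
Normalized log2 signal minus the mean of the siNC arrays for 10 named genes, with each point an array, circles for slide 1, squares for slide 2, and bars the group mean ± SD (n = 3). For CA9 the sicircTNRC6B mean lies 1.58 above the siNC mean and for CD8A 1.56 below it, where siNC replicate 1 lies between the other siNC arrays and the sicircTNRC6B arrays.

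Of the 30 lists tested, camera with the preset correlation called 5, of which 4 were higher and 1 was lower in sicircTNRC6B. Replication-dependent histone genes, which supply nucleosomes in S phase, were higher as a list: all 45 tested members had a positive difference, with a median of 0.64 (adjusted p = 1.16e-11 by limma's camera, and adjusted p = 0.896 with an estimated correlation). Within slide 1, against 1 siNC array, 20 of the 45 were positive, where the median of all features was -0.084. Of the 45 members 0 passed the threshold singly. Among them H2BC17 had 0.80 (SE 0.23), H2BC5 0.93 (SE 0.28), H2BC13 0.78 (SE 0.23) and H2BC9 0.89 (SE 0.27). Hypoxia and glycolysis genes rose as a list, with 29 of 32 members positive and a median of 0.29 (adjusted p = 4.36e-05 by camera, and adjusted p = 0.896 with an estimated correlation). CA9 and NDRG1 led it, followed by ALDOC, a glycolytic aldolase, at 0.99 (SE 0.22) and KDM3A, a hypoxia-inducible histone demethylase, at 0.97 (SE 0.27), which normexp background correction shrank to 0.48 and 0.28. Within slide 1 KDM3A had 0.41. The list median was 0.12 with quantile normalization and with the deposited table. Cytosolic ribosomal protein genes rose as a list with 41 of 42 members positive and a median of 0.26 (adjusted p = 0.000701, and adjusted p = 0.896 with an estimated correlation), and included RPLP1 at 0.49, RPL9 at 0.42, RPS23 at 0.56 and RPS18 at 0.39. A dimmer RPS23 probe gave -0.12. Heat shock protein genes rose as a list with 25 of 26 members positive and a median of 0.23 (adjusted p = 0.00553, and adjusted p = 0.896 with an estimated correlation), among them DNAJA1 at 0.50, DNAJB4 at 0.45, HSPA1B at 0.39 and HSPA1A at 0.39. Leukocyte markers fell as a list, with 7 of 10 tested members negative and a median of -0.27 (adjusted p = 0.0267, and adjusted p = 0.896 with an estimated correlation): CD8A at -1.56, CD14 at -0.55 and PTPRC at -0.46, and AIF1, above background on 1 of the 3 sicircTNRC6B arrays, at -1.20. With normexp background correction the list median was -0.14 and these genes had -0.56, -0.28, -0.20 and -0.32. On probes above background on all 6 arrays the median was -0.08 (adjusted p = 0.0732). With an estimated correlation camera called 0 lists, and fry called 0. No list member passed over all genes, and 9 passed adjusted over the list alone: CA9, NDRG1 and ALDOC of hypoxia and glycolysis, CD8A and AIF1 of leukocyte markers, COL1A1 and C1R of fibroblast markers, OAS1 of interferon-stimulated genes, which was above background on no siNC array, and DKK1 of Wnt targets. This adjustment did not correct for the number of lists. COL1A1, also a member of mesenchymal transition, did not pass there (adjusted p = 0.0862 by limma over that list). COL1A1 and C1R had 0.93 and 0.98 over both slides, against 0.47 and 0.46 within slide 1. OAS1 had 0.84 and 0.83. With the slide as a block, which compares siNC replicate 1 with the sicircTNRC6B arrays, 0 of the 5 lists were called, and the medians within slide 1 were -0.035 for histones, -0.080 for hypoxia and glycolysis, -0.12 for ribosomal proteins, -0.029 for heat shock proteins and -0.28 for leukocyte markers, each against 1 siNC array. Fitted on slide 1 alone, camera with the preset correlation called leukocyte markers lower (adjusted p = 0.0374, against 0.0976 with the block) and not the other 4; with the block, leukocyte markers had an adjusted p = 0.997 with an estimated correlation, and on slide 1 alone an adjusted p = 0.999 with an estimated correlation. Quantile normalization ended the calls of ribosomal proteins (median 0.023, adjusted p = 0.476), heat shock proteins (median 0.11, adjusted p = 0.080) and leukocyte markers (median -0.26, adjusted p = 0.113), and leaving out sicircTNRC6B replicate 1 ended those of heat shock proteins and leukocyte markers.

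**Figure D2:**
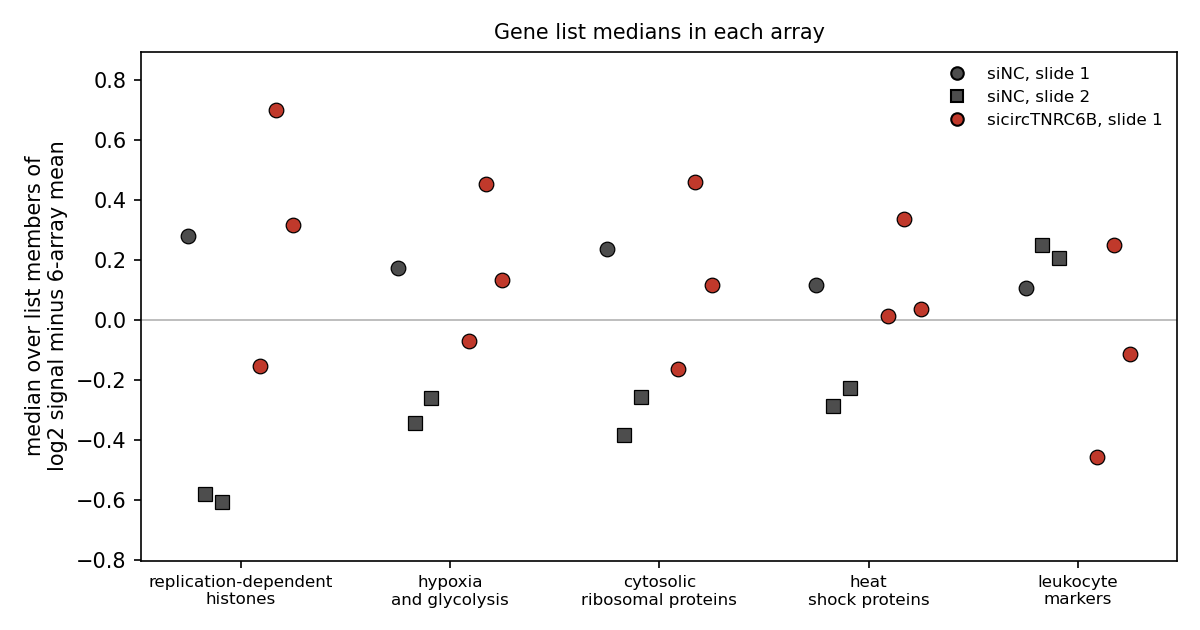
Median over list members of log2 signal minus the mean of the 6 arrays, for the 5 lists past the threshold, with each point an array, circles for slide 1 and squares for slide 2. For histones, siNC replicates 2 and 3 lie at -0.58 and -0.61, while siNC replicate 1 lies at 0.28, among the sicircTNRC6B arrays at -0.15, 0.70 and 0.32.

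Squamous and epithelial lists were not called by camera in the setting chosen beforehand. Basal squamous identity genes had a median of 0.18 over 24 members (adjusted p = 0.0858), with the basal keratin KRT15 at 0.93, but camera with the preset correlation called them higher with normexp (adjusted p = 0.0140), without the filter on dim probes (adjusted p = 0.00139) and with the mean of a gene's probes (adjusted p = 0.0435). These calls had adjusted p = 0.938, adjusted p = 0.856 and adjusted p = 0.862 with an estimated correlation. Within slide 1, against 1 siNC array, the median of basal squamous identity was -0.15, where the median of all features was -0.084. Squamous differentiation genes had a median of -0.0055 and a mean of 0.018 (adjusted p = 0.749), with the transglutaminase TGM1 at 0.75. Epithelial adhesion had a median of 0.08 (adjusted p = 0.578) with the desmosomal gene DSP at 0.31, and mesenchymal transition 0.13 (adjusted p = 0.330) with COL1A1 at 0.93. Matrix proteases and invasion had a median of -0.019 and a mean of 0.00036 (adjusted p = 0.601), with MMP9 at -0.76.

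Proliferation, survival and repair lists were not called either. The medians by camera were 0.13 for G1/S and DNA replication (adjusted p = 0.426, CCND1 at -0.41), -0.0017 for G2/M and mitosis (adjusted p = 0.578, MAD2L1 at -0.33), 0.08 for DNA repair (adjusted p = 0.578, MRE11 at 0.50) and 0.12 for MYC targets and ribosome biogenesis (adjusted p = 0.297, NOLC1 at 0.54). Targets of p53 had a median of -0.0051 and a mean of 0.048 (adjusted p = 0.578, TIGAR at -0.61), and apoptosis regulators 0.06 (adjusted p = 0.578). With normexp, camera with the preset correlation called G1/S and DNA replication (adjusted p = 0.0274) and MYC targets and ribosome biogenesis (adjusted p = 0.0140) higher, the latter also without the filter on dim probes (adjusted p = 0.0171). Both had an adjusted p = 0.938 with an estimated correlation under normexp, and the last call an adjusted p = 0.856 with an estimated correlation. Within slide 1, against 1 siNC array, the medians were -0.031 for G1/S and DNA replication and -0.15 for MYC targets and ribosome biogenesis. The median of all features there was -0.084.

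Signalling lists gave medians of -0.17 for YAP/TEAD targets (adjusted p = 0.0618, RBMS3 at -0.56), 0.22 for TGF-beta targets (adjusted p = 0.0740, KLF10 at 0.92), 0.15 for Wnt targets (adjusted p = 0.864, DKK1 at -0.76) and 0.11 for Notch targets (adjusted p = 0.330, NRARP at 0.62). Immediate early genes had 0.09 (adjusted p = 0.593, NR4A3, above background on 1 of the 3 sicircTNRC6B arrays, at -1.08), NF-kB and inflammatory cytokines -0.0064 (adjusted p = 0.297, IL6 at -0.75), and interferon-stimulated genes 0.025 (adjusted p = 0.562), among which OAS1, a sensor of double-stranded RNA, was above background on no siNC array and was at least 1.63-fold higher in sicircTNRC6B. Small RNA silencing machinery had a median of 0.054 but a mean of -0.025 (adjusted p = 0.562). Camera with the preset correlation called YAP/TEAD targets lower with quantile normalization (adjusted p = 0.00643), the deposited table (adjusted p = 0.00661), probes above background on all 6 arrays (adjusted p = 0.0431), without siNC replicate 2 (adjusted p = 0.0216) and after removal of the probe GC and signal trend (adjusted p = 0.00483). In that order these calls had adjusted p = 0.286, 0.288, 0.910, 0.993 and 0.416 with an estimated correlation. It called TGF-beta targets higher without the filter on dim probes (adjusted p = 0.00139) and after removal of that trend (adjusted p = 0.0406), which had adjusted p = 0.856 and adjusted p = 0.764 with an estimated correlation. The median of TGF-beta targets within slide 1, against 1 siNC array, was -0.11, where the median of all features was -0.084. Calls of YAP/TEAD targets, inflammatory cytokines and interferon-stimulated genes with the slide as a block, against 1 siNC array, are described below with their medians.

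Metabolic and stress lists gave medians of 0.21 for oxidative phosphorylation (adjusted p = 0.0858, ATP5PB at 0.38), 0.12 for cholesterol and fatty acid synthesis (adjusted p = 0.330), 0.15 for NRF2 targets (adjusted p = 0.578, ME1 at 0.95), 0.12 for autophagy and lysosome (adjusted p = 0.556, ATP6V1H at 1.00) and -0.05 for the unfolded protein response and ATF4 targets (adjusted p = 0.330, SLC7A11 at -0.67). Within slide 1, against 1 siNC array, ATP5PB had 0.029, ME1 0.54, ATP6V1H 0.044 and SLC7A11 -0.29. Camera with the preset correlation called oxidative phosphorylation higher with normexp (adjusted p = 0.000706), without the filter on dim probes (adjusted p = 0.00228) and without siNC replicate 1 (adjusted p = 0.00822), and lower with the slide as a block (adjusted p = 0.0422). In that order these calls had adjusted p = 0.938, 0.856, 0.976 and 0.997 with an estimated correlation. It called the unfolded protein response and ATF4 targets lower with quantile normalization (adjusted p = 0.00687), the deposited table (adjusted p = 0.00736) and after removal of the probe GC and signal trend (adjusted p = 0.00318). These had adjusted p = 0.286, 0.288 and 0.416 with an estimated correlation. The call of that list with the slide as a block, against 1 siNC array, is described below with its median. Cholesterol and fatty acid synthesis was called higher with normexp (adjusted p = 0.0374, and adjusted p = 0.938 with an estimated correlation). Its median within slide 1, against 1 siNC array, was -0.091, where the median of all features was -0.084. Among markers of other cell types, fibroblast markers had a median of 0.24 over 7 tested members (adjusted p = 0.0858). Of 18 endothelial markers, 3 were tested, too few for camera, and MMRN2 had -0.80, against -0.13 within slide 1.

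Genes above background in a single group were few. On all sicircTNRC6B arrays and no siNC array there were 61 named genes, and on all siNC arrays and no sicircTNRC6B array 20. The sicircTNRC6B arrays also had more probes well above background (25564, 25468 and 25424) than the siNC arrays (24262, 25238 and 23666). Such genes were not counted for other splits of the arrays, so the imbalance is given without a reading. HLA-DQB1, a class II antigen-presentation gene, was at least 3.08-fold higher in siNC, RNASE13 at least 2.87-fold, GCNT2, a glycan-branching enzyme gene, at least 2.43-fold and SLC25A45 at least 2.35-fold. DUSP13A, a phosphatase gene, was at least 2.25-fold higher in sicircTNRC6B. Limma's test of these genes, on the probes' own values, gave each an adjusted p of 0.585. The bounds themselves were not tested. On slide 1, siNC replicate 1 had log2 levels of -1.84 for HLA-DQB1, -2.78 for RNASE13, -2.50 for GCNT2 and -2.50 for SLC25A45, against siNC means of -1.34, -1.51, -1.75 and -1.80. For RNASE13, GCNT2 and SLC25A45 the siNC mean was thus raised mostly by siNC replicates 2 and 3 on slide 2. Replicate 1, a single array, lay above the sicircTNRC6B means of -3.555, -3.55 and -3.472, which are levels not well above background. The choice required replicate 1 to be well above background and every sicircTNRC6B array not to be. This order therefore follows from the choice and lends these genes no support.

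The arrays did not separate by treatment on the first principal component. It held 57.6% of the variance and set siNC replicates 2 and 3 of slide 2 at one end, with sicircTNRC6B replicate 1 at 6.38 between them and the other 3 arrays of slide 1, and the second, with 24.2%, set sicircTNRC6B replicate 1 apart. Across features, siNC replicate 1 correlated at 0.993 with sicircTNRC6B replicates 2 and 3, at 0.976 with siNC replicate 2 and at 0.974 with siNC replicate 3. Not all pairs followed the slide: sicircTNRC6B replicates 1 and 2, on 1 slide, correlated at 0.970, below siNC replicate 2 with sicircTNRC6B replicates 1 (0.977) and 3 (0.976) on the other. Genes are not independent replicates. Without siNC replicate 1, where slide and treatment coincide, limma called 538 named genes, 354 higher and 184 lower in sicircTNRC6B, including CA9 at 1.67, TNNI2 at 1.34, H2BC5 at 1.22 and CD8A at -1.97, against 1.41, 1.41, 0.37 and -0.74 within slide 1. In these examples all sicircTNRC6B arrays lay beyond all siNC arrays, replicate 1 included, so their signs within slide 1 were fixed. Of the 538 genes, 320 had the same sign within slide 1, a count that shares the sicircTNRC6B arrays with their choice. That count has no reference value for no change, so it decides nothing. With the slide as a fixed block limma called 0 named genes, 229 having an unadjusted p under 0.05, and with it as a random block 0, with 373 at that level.

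**Figure D3:**
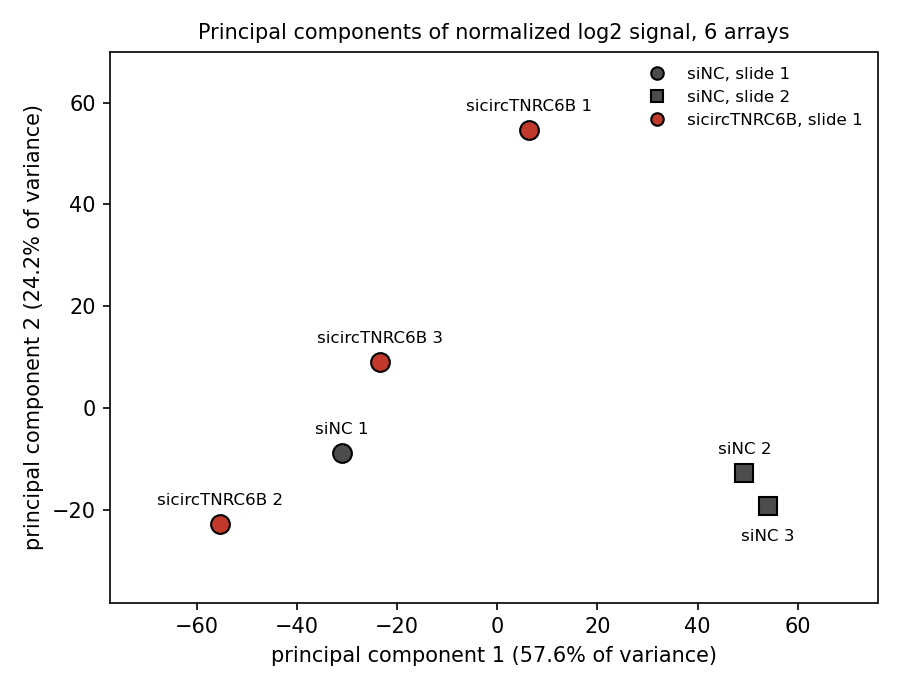
First and second principal components of normalized log2 signal across the 6 arrays, in component units, with circles for slide 1 and squares for slide 2. On the first component siNC replicates 2 and 3 lie at 49.3 and 54.0 and siNC replicate 1 at -31.0, between sicircTNRC6B replicates 2 and 3 at -55.3 and -23.4, while sicircTNRC6B replicate 1 lies at 6.38.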

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

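Slide as a random block, slide 1 alone and removal of the trend over probe GC content and signal were chosen after the data were seen. TNRC6B kept its sign and missed the threshold under every setting run, from -0.43 with quantile normalization or the deposited table to -0.27 with normexp, and between -0.39 and -0.31 with an array left out (adjusted p from 0.218 to 1.00 over all settings). In the setting chosen beforehand 847 named genes had an unadjusted p under 0.05 and 180 under 0.01, against 367 and 144 with median scaling. Named genes called numbered 9 with median scaling (2 higher, 7 lower, 9 at least 2-fold). With an array left out they ranged from 0 to 538 (higher 0 to 354, lower 0 to 184, at least 2-fold 0 to 447), and the high value came from leaving out siNC replicate 1. Called lists numbered 10 with normexp, 9 without the filter on dim probes, 0 with an estimated correlation, alone or with any other setting (a pairing added after the data were seen), 0 with fry, and 3 to 5 with an array left out; they were not run with the slide as a random block. Histones and hypoxia and glycolysis kept their calls under every setting of camera except an estimated correlation and both settings that compare within slide 1, but the median of hypoxia and glycolysis was 0.12 with quantile normalization and the deposited table. Ribosomal proteins lost theirs also with quantile normalization, the deposited table, and without siNC replicate 2 or sicircTNRC6B replicate 2, heat shock proteins with both of those scalings, median scaling and without sicircTNRC6B replicate 1, and leukocyte markers with both of those scalings, without siNC replicate 1 or sicircTNRC6B replicate 1, with probes above background on all 6 arrays and with the slide as a block, though not on slide 1 alone (adjusted p = 0.0374, resting on 1 siNC array); ribosomal proteins (median 0.025) and leukocyte markers (median -0.23, little moved) also lost theirs after removal of the trend. With the replicate number as a block, 0 named genes and 5 lists were called and TNRC6B stayed at -0.36. The values gave no sign that the numbers pair the samples: deviations of same-numbered arrays correlated at -0.41, -0.38 and 0.03, and no siNC array correlated best with its own number. These deviations also hold the slide difference and the probe trend, so they cannot show whether same-numbered cultures were handled together. With the slide as a fixed block, and equally within slide 1, the signs of TNRC6C (-0.31), AGO1 (-0.030), AGO3 (0.023), AGO4 (0.010), DAG1 (0.12), RPS23 (-0.13) and the ribosomal protein list (median -0.12) turned, as did the medians of histones (-0.035), hypoxia and glycolysis (-0.080) and heat shock proteins (-0.029), where the median of all features was -0.084. With the slide as a random block TNRC6C (-0.062) and DAG1 (0.035) turned. DAG1 also turned with normexp (0.039), without siNC replicate 3 and without sicircTNRC6B replicate 1 (range with an array left out -0.11 to 0.13), TNRC6C without siNC replicate 2 and without sicircTNRC6B replicate 2 (range -0.28 to 0.53), and SFTA1P with the mean of its probes (0.040), since its probes disagree. The cause of the other turns was not tested. Without siNC replicate 1, 16 of the other 44 named genes passed the threshold. Signal over background left at most 43.9% of the probes well above background on any array.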

Other observations

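The tests of the gene lists within slide 1, the settings that take slide 1 alone or remove the probe GC and signal trend, the estimated correlation under these settings, and the count of other splits for genes were chosen after the result was seen.

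With the slide as a block, the comparison rests on siNC replicate 1 as the lone control, and its list values are given without a reading. Camera with the preset correlation called 7 lists, 0 of them among the 5 called over both slides, and each of the 7 had an adjusted p = 0.997 with an estimated correlation and an adjusted p of 0.95 by fry. The medians within slide 1 were -0.27 for the unfolded protein response and ATF4 targets, -0.26 for YAP/TEAD targets, -0.17 for NF-kB and inflammatory cytokines, -0.17 for oxidative phosphorylation, 0.15 for interferon-stimulated genes, 0.098 for DNA repair and 0.086 for fibroblast markers, where the median of all features was -0.084.

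siNC replicate 1 lay nearer the sicircTNRC6B arrays than the other siNC arrays. A batch of slide or scan is a candidate explanation: in the 7 spike-in controls, which carry no RNA of the cells, its mean log2 distance was 0.839 to the other siNC arrays and 0.092 to the sicircTNRC6B arrays, a difference of 0.75, against an SD of 0.053 among distances within slide 1. A wrong label on siNC replicate 1 stays open as well. Taken alone against the 3 other arrays of slide 1, it gave 117 named genes at an unadjusted p under 0.05, between the 17 of sicircTNRC6B replicate 3 and the 3647 of sicircTNRC6B replicate 1. TNRC6B at 2.27 in siNC replicate 1, near 2.35 and 2.34 in the other siNC arrays, is a single gene and excludes nothing.

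Histone genes and hypoxia and glycolysis genes were higher in sicircTNRC6B over both slides by camera with the preset correlation (adjusted p = 0.896 with an estimated correlation, 0.809 and 0.784 by fry), and slide or scan may account for these list shifts: within slide 1 the medians were -0.035 and -0.080, against 0.64 and 0.29 over both slides. The median of all features was -0.084 within slide 1 and 0.049 over both slides. A trend over probe GC content and signal is argued against as the whole cause for the histones, whose median was 0.56 after its removal (adjusted p = 8.17e-15 by camera with the preset correlation, and adjusted p = 0.557 with an estimated correlation), and cannot be told apart for hypoxia and glycolysis, at 0.14 (adjusted p = 0.002, and adjusted p = 0.557 with an estimated correlation), because the median shrank while the list stayed past the threshold with the preset correlation. An effect of the siRNA is the biological explanation the design names, and it stays open: with the slide as a block, against 1 siNC array, neither list was called (adjusted p = 0.0524 for histones and 0.108 for hypoxia and glycolysis). Of the 10 splits of the 6 arrays into 3 and 3, 5 gave at least the 5 lists of the real split and the highest other gave 7; so few splits cannot give a share under 0.05.

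For genes, all 10 splits gave at least the 0 of the real split, as any split must, so this count tests nothing, but the split of siNC replicate 1 and sicircTNRC6B replicates 2 and 3 against the rest gave 3396, which points to a structure of the samples. A trend over probe GC content and signal is a candidate for part of it, since the split gave 1496 after its removal, and deviations of sicircTNRC6B replicates 1 and 2 correlated with probe GC content at -0.476 and 0.307 across features. An exchange of labels between siNC replicate 1 and sicircTNRC6B replicate 1 cannot be told apart from a shared quality of those arrays. After the trend was removed, siNC replicate 1 minus sicircTNRC6B replicate 1 followed sicircTNRC6B replicates 2 and 3 minus siNC replicates 2 and 3 with r = 0.285 across features, where 0.3 had been set as the value an exchange needs and 0.1 as the value against it. No biological explanation was tested for this split, which no label names.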
